A study of Homo sapiens with 12 samples.

How the data were processed

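The deposited table gave, for 27911 gene symbols, a value in each of 12 libraries, made from total RNA extracted on silica columns and prepared with a kit for Illumina sequencing, per the labels' protocols. The signal values in the deposited table are gene read counts divided by 1 size factor per library, as the authors' name for the table (DESeq2-normalised counts) and the values themselves show. TopHat, SAMtools, HTSeq and DESeq2 and the genome build hg19 are named without versions or order, per the submitters' processing notes. The gene annotation, the counting strand, any filter and the parameters are not given in the sources used here, so the values of antisense and overlapping genes and those of near-identical gene families are uncertain. Whole reads were recovered from the steps of the values: 100% of values in every library were whole within a tolerance of 0.01, the recovered size factors of 0.870 to 1.18 equalled those of the median-of-ratios method, and the totals were 9196715 to 11891236 reads. For VGLL1 replicate 3 the factor of 1.01 lies close to 1, and its values are still whole multiples of 1 step. With no read for a gene in a library, the limit of 3 counts allowed a level of 0.252 to 0.326 CPM. The table held 0 mitochondrially encoded symbols.

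Groups and replicate numbers came from the sample titles, and columns were matched to samples by those names. The characteristics name the treatment of each sample as none, while the growth protocol puts 100 and 1000 nM fulvestrant in the medium of FULVR-1 and FULVR-2, and the doses here follow the protocol. The titles call the FULVR replicates biological and leave the others unqualified. The main test was limma 3.58.1 (lmFit, contrasts.fit and eBayes with a trend, two-sided) on log2(value + 1) over genes with a value of at least 10 in at least 3 libraries, 13952 genes, with the 12 libraries in 1 fit of 4 group means and Benjamini-Hochberg adjustment at 0.05. Of the 6 comparisons, 4 were main ones and the 2 of resistant lines against Vector were secondary. Gene lists, 22 in number and fixed before the data were examined, were tested with camera in limma at a preset correlation of 0.01, adjusted over the 21 lists with at least 5 tested members in each comparison. The list of mitochondrially encoded genes could not be tested. Across the comparisons 60 list tests passed, and 29 of these also passed with an estimated correlation. Of 362 list symbols 347 were found, where needed under older names such as CYR61 and CTGF. The named genes were, by a rule fixed before the data were examined, the 10 largest increases and 10 largest decreases of each main comparison among genes past the threshold with a mean of at least 100 in the higher group and no overlap of replicates, the 8 genes VGLL1, ESR1, PGR, GREB1, TFF1, EGFR, CYR61 and CTGF, and up to 4 members of each list past the threshold with the largest change. A member named for its direction alone within a count was chosen after its values were seen. Folds against a group with no reads used a floor of 3 counts over the group, and ratios with 1 to 3 reads in a group carry a 95% counting interval.

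Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 50, TMM rescaling, quantile normalisation, a fit of only the 2 groups compared, a replicate block, sample quality weights, each replicate left out in turn, an estimated correlation and a rotation test (fry) for the lists. The count models edgeR 4.0.16 (quasi-likelihood with TMM) and DESeq2 1.42.0 were run on the recovered whole reads and called 687 and 758 genes for VGLL1 against Vector cells, where limma called 666. For FULVR-1 against VGLL1 they called 9442 and 8863, for FULVR-2 against VGLL1 9943 and 9477, and for FULVR-2 against FULVR-1 8351 and 7500. The limma test was tested on simulated data, counts drawn for the real genes with known changes: for VGLL1 against Vector, over 13673 genes, it recovered 69.4%, 84.3% and 97.1% of genes changed 1.5-, 2- and 4-fold, and 4.55% of its calls were false. Over the 6 comparisons it recovered 65.3% to 77.6%, 76.2% to 87.0% and 88.7% to 97.1%, and 3.91% to 8.67% of its calls were false. That share passed the 5% aimed at in 4 of them and was highest for FULVR-2 against FULVR-1. Few genes were changed in the simulation, for VGLL1 against Vector 62, 70 and 68 by 1.5-, 2- and 4-fold, with directions drawn at random. The real comparisons with a resistant line called 59.0% to 70.8% of the genes tested, so these rates need not hold for them. On the simulated data camera called 6 of 6 raised sets and, before adjustment, also 1 of 6 unchanged sets, that of VGLL1 against Vector. Simulated counts were drawn independently for each gene. They therefore do not check camera on lists of correlated genes, such as cholesterol synthesis genes with an estimated correlation of 0.31. Overlaps between comparisons that share libraries were set beside 50 simulations of unchanged groups. Transcript length and GC content came from GENCODE transcripts of GRCh38, matched for 21003 symbols, and the order of neighbouring genes from RefSeq on GRCh38. Because that build differs from hg19, no coordinates are given. Work was done in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9) and R 4.3.3.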

Results

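RNA was sequenced from MCF7 cells, an established estrogen receptor-positive human breast cancer line, that carried ActCas9, read here as a Cas9-based gene activation system. There were 12 libraries in 4 groups of 3. Vector cells, called parental in the series design text, have the system but no target gene in their titles and were kept in the same selection antibiotics, and VGLL1 cells carried it for VGLL1, which encodes a vestigial-like protein that binds TEAD transcription factors. FULVR-1 and FULVR-2 were VGLL1-activated lines resistant to fulvestrant, a drug that binds the estrogen receptor and leads to its degradation, and were kept in 100 and 1000 nM of it. The libraries held 9196715 to 11891236 reads assigned to genes. Gene levels are given as size-factor-normalised read counts, as means ± SD over the 3 libraries of a group unless a sentence says otherwise, and log2 fold changes are on the log2(value + 1) scale, which understates the change of low genes. Nothing in the labels says that the Vector and VGLL1 libraries came from separate cultures, so p-values there measure the spread between these samples, which may be technical. Each FULVR group is replicates of 1 line, so p-values of its comparisons measure the spread within that line and not between resistant lines. For Vector and VGLL1 cells the labels name no separately derived lines either. Pairs of replicates differed by a chi-square per gene of 1.47 to 2.99, except that FULVR-1 replicate 2 differed from replicates 1 and 3 by 7.63 and 8.63. No pair differed by less than the sampling noise. A principal component analysis put 75.2% of the variance on a component that set both FULVR groups apart from Vector and VGLL1 cells, and 15.9% on a component that set FULVR-1 apart from FULVR-2.

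The activated gene was measured at 4.53, 7.51 and 3.35 normalised counts in Vector replicates 1 to 3 and at 201, 208 and 223 in the VGLL1 replicates. In FULVR-1 it stood at 4009.7, 4115 and 3947, and in FULVR-2 at 5916, 5529.6 and 5261. VGLL1 was thus 41.1-fold higher in VGLL1 than in Vector cells (limma, adjusted p = 2.1e-13), 19.1-fold higher in FULVR-1 than in VGLL1 cells (limma, adjusted p = 3.0e-14) and 26.4-fold higher in FULVR-2 than in VGLL1 cells (limma, adjusted p = 3.3e-15). FULVR-2 cells held 1.38-fold more VGLL1 than FULVR-1 cells (limma, adjusted p = 0.0125), and without FULVR-2 replicate 1 that difference missed the threshold (limma, adjusted p = 0.0518).

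**Figure D1:**
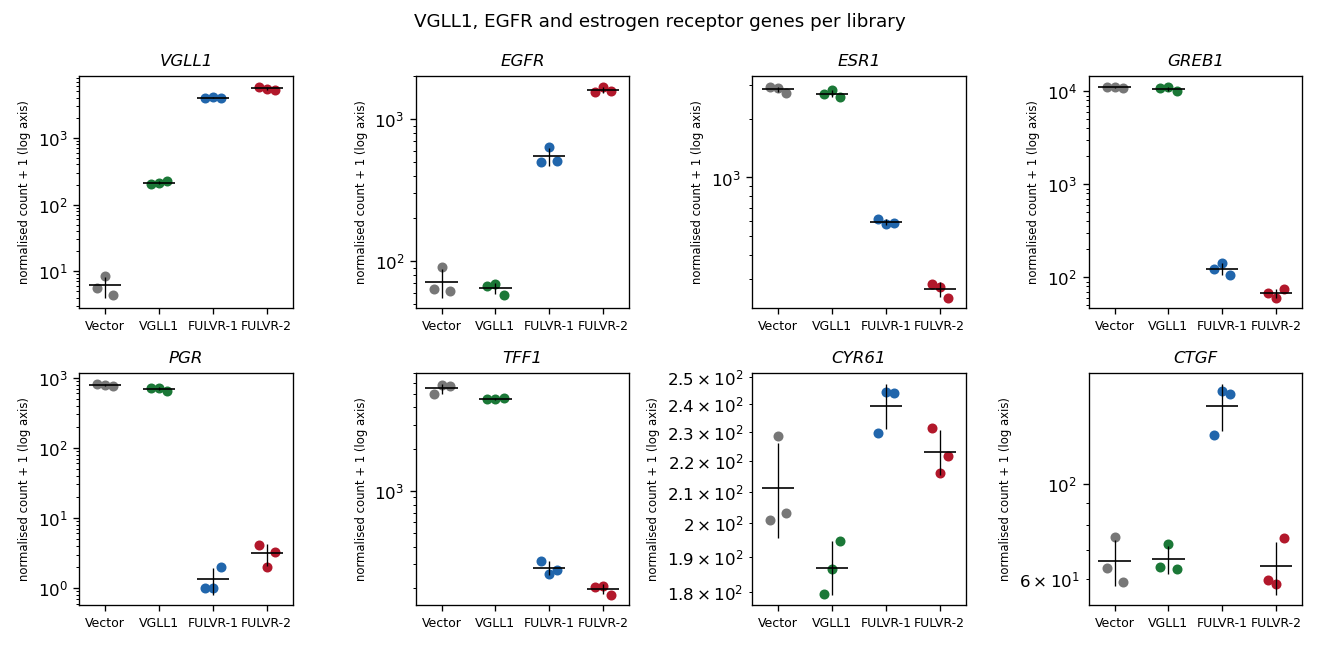
Normalised counts plus 1, on a log axis, of 8 genes fixed before the data were examined (VGLL1, EGFR, ESR1, GREB1, PGR, TFF1, CYR61 and CTGF) in the 4 groups, where each point is a library, the horizontal bar is the group mean and the vertical bar is ± SD. VGLL1 stood at 211 in VGLL1 cells and at 4024 and 5569 in the resistant lines, and ESR1 at 588 and 266 in the resistant lines.

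The comparison of VGLL1 with Vector cells asked what differed with activation of VGLL1. If the control cells lacked the activation system, its effect would be included. The keratin genes KRT17 and KRT81 fell from 142 ± 11.2 to 90.2 ± 2.95 (log2 fold change -0.64 ± 0.09 (SE)) and from 579 ± 28.2 to 389.6 ± 44.2 (log2 fold change -0.58 ± 0.07 (SE)). The interferon-stimulated gene IFI6 fell from 580.0 ± 62.5 to 325 ± 40.2, a log2 fold change of -0.83 ± 0.10 (SE) (limma, adjusted p = 8.2e-04). SEMA5A, a semaphorin, rose 1.77-fold to 132 ± 14.2, and EGR1, an immediate early transcription factor, rose 1.46-fold to 1640.3 ± 109. ESR1, which encodes the estrogen receptor, stood at 2833 ± 96.0 in Vector and 2697 ± 118 in VGLL1 cells (limma, adjusted p = 0.537), and EGFR at 71.0 ± 16.6 and 63.7 ± 5.57 (limma, adjusted p = 0.584). The receptor's target genes PGR, GREB1 and TFF1 had log2 fold changes of -0.19, -0.06 and -0.24, and the YAP/TEAD targets CYR61 and CTGF of -0.17 and 0.02, none past the threshold (limma, adjusted p = 0.724, 0.743, 0.0771, 0.225 and 0.96).

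Of the interferon-stimulated genes, 7 of 21 fell and none rose in VGLL1 cells, and 12 fell when adjusted over the list alone (median log2 fold change -0.29, camera adjusted p = 1.2e-05). OAS1 fell from 18.4 ± 5.44 to 7.71 ± 1.29, and IFIT1 and IFIT3 had log2 fold changes of -0.76 and -0.67. Of the estrogen-repressed genes, 5 of 14 rose, 8 when adjusted over the list alone (median 0.20, camera adjusted p = 1.0e-04), among them LYPD3 (log2 fold change 0.50), CCNG2 (0.32), BMF (0.48) and TP53INP1 (0.29). Of the proliferation genes, 6 of 24 fell, 11 when adjusted over the list alone (median -0.13, camera adjusted p = 2.5e-04), with MYBL2 at -0.25, RRM2 at -0.23 and FOXM1 at -0.23, and this list had adjusted p = 0.454 with an estimated correlation. The ABC drug transporters ABCC4 and ABCC5 rose by 0.50 and 0.25, 2 of 6 on their list and 4 when adjusted over the list alone (median 0.15, camera adjusted p = 0.0221). That list had adjusted p = 0.132 with an estimated correlation, and without Vector replicate 1 or VGLL1 replicate 1 it missed the threshold as well (camera adjusted p = 0.0559 and 0.058). The calls of the interferon-stimulated and estrogen-repressed lists held with an estimated correlation. Markers of non-epithelial cells did not differ as a list (median 0.18, camera adjusted p = 0.387), with 1 of 10 past the threshold, COL1A1 (log2 fold change 0.24).

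The other 16 lists tested did not pass in this comparison (camera adjusted p from 0.243 to 0.853). Estrogen-induced genes had a median log2 fold change of -0.08, with SIAH2 and FKBP4 the 2 of 29 that fell, also when adjusted over the list alone. YAP/TEAD target genes had a median of -0.02, with TGFB2 (log2 fold change -0.32) the 1 of 20 past the threshold. Basal epithelial markers had a median of -0.25, or -0.18 with KRT14 at its bound, and KRT16 and KRT17 fell. The p53 targets PHLDA3, AEN and CDKN1A fell (log2 fold change -0.36, -0.29 and -0.27), 3 of 16 on that list. Medians of the rest were -0.01 for vestigial-like, TEAD and YAP/TAZ genes, -0.12 for MAPK output genes, 0.03 for immediate early genes, -0.05 for luminal markers, 0.01 for mesenchymal markers and 0.04 for cholesterol synthesis. Hypoxia and glycolysis genes had a median of -0.04, unfolded protein and ATF4 response genes -0.02, the BCL2 family -0.10, the chromosomal neighbours of VGLL1 -0.07 and replication-dependent histone genes -0.12. ERBB receptors and ligands had a mean of -0.03, with ERBB3 (log2 fold change 0.23) past the threshold. For the ERBB, unfolded protein, vestigial-like, YAP/TEAD and luminal lists the median, the mean and the direction of the test differed in sign.

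In all, 666 of 13952 genes tested differed between VGLL1 and Vector cells (limma, adjusted p under 0.05), 340 higher and 326 lower, of which 23 and 8 by at least 2-fold. Those 2-fold counts depended on the libraries and the method. They became 2 and 4 without VGLL1 replicate 1, 3 and 5 without VGLL1 replicate 2, 10 and 4 without Vector replicate 1, and 38 and 9 without Vector replicate 3. They were 6 and 1 with a pseudocount of 5, 54 and 20 with sample quality weights and 1 and 3 in DESeq2. The other genes named by rule were FER1L4, SLC9A5, MYO15B, LINC00641, CSAD, ENO3 and RHBG, which rose by 0.61 to 0.76 on the log2 scale, and PKIB, SULF1, TAGLN, ARHGAP22, CCNO, LMCD1 and LYSMD2, with log2 fold changes of -0.78 to -0.50. SLC25A25-AS1 (log2 fold change 0.73) is antisense and its counting strand is not given in the sources used here, so its value is uncertain. With TMM rescaling 374 genes were higher and 205 lower, with quantile normalisation 342 and 179, and the count fell to 110 without Vector replicate 1, 172 without Vector replicate 2, 46 without VGLL1 replicate 1 and 72 without VGLL1 replicate 2. It was 553 without Vector replicate 3 and 548 without VGLL1 replicate 3. Of 47 named genes past the threshold, 11 passed it under every alternative run, namely VGLL1, CCNO, EGR1, FER1L4, IFI6, KRT17, KRT81, LYPD3, MYO15B, PKIB and SEMA5A.

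FULVR-1 cells were set against VGLL1 cells to ask how the line resistant at 100 nM fulvestrant differed from the line without the drug. For either resistant line against VGLL1 or Vector cells, the presence of the drug, selection and the line itself cannot be separated. ESR1 fell from 2697 ± 118 to 588 ± 19.9, 4.59-fold lower (limma, adjusted p = 1.1e-15), and 3 of its target genes fell by more. PGR, the progesterone receptor, fell from 694 ± 35.1 to 0.329 ± 0.570, where 1 read remained (ratio 2108, counting interval 386 to 85072), GREB1 fell 87.0-fold to 122 ± 18.3 and TFF1 16.5-fold to 280.0 ± 31.6. BCL2, an inhibitor of apoptosis, fell from 1859.6 ± 76.2 to 3.10 ± 1.74. EGFR rose 8.57-fold to 545 ± 76.7 (limma, adjusted p = 3.3e-13), the vascular cadherin CDH5 rose from 0.933 ± 0.906 to 556 ± 54.5, and EPAS1, a hypoxia-inducible transcription factor, rose 174-fold to 6647 ± 140.2. CTGF and CYR61 had log2 fold changes of 1.18 ± 0.15 (SE) and 0.36 ± 0.08 (SE) (limma, adjusted p = 1.1e-06 and 8.3e-04).

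Estrogen-induced genes fell in 26 of 29 cases (median log2 fold change -1.95, camera adjusted p = 1.4e-10), led by PGR, PDZK1 (-6.49), GREB1 (-6.44) and the carbonic anhydrase CA12 (-5.81), while CCND1, NRIP1 and CTSD rose. Estrogen-repressed genes rose in 12 of 14 cases (median 1.39, camera adjusted p = 1.0e-04), with PSCA at 3.24, BCAS1 at 3.15 and BMF, a pro-apoptotic BCL2 relative, at 2.97. All 24 proliferation genes fell (median -1.16, camera adjusted p = 4.3e-11), with MYBL2 at -1.71 and FOXM1 at -1.59. The 21 interferon-stimulated genes all rose (median 2.15, camera adjusted p = 7.0e-09), for example OAS1 from 7.71 ± 1.29 to 189 ± 7.42 and IFIT3 from 9.90 ± 0.919 to 159 ± 15.7. Targets of p53 rose in 15 of 16 cases, 16 when adjusted over the list alone (median 1.16, camera adjusted p = 6.0e-07), including GDF15 (3.51), BTG2 (3.05) and FAS (2.99). Basal epithelial markers rose in 10 of 12 cases (median 1.68, also with KRT14 at its bound, camera adjusted p = 1.1e-04), among them the laminin chains LAMC2 (5.45) and LAMB3 (2.94), KRT16 (4.38) and CAV1 (3.87).

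MAPK output genes rose in 11 of 13 cases in FULVR-1 cells (median 2.21, camera adjusted p = 1.1e-04), with DUSP4 at 4.81, ETV5 at 4.36 and FOSL1 at 3.25, while EPHA4 fell. Immediate early genes rose in 11 of 14 cases and fell in 2 (median 1.01, camera adjusted p = 6.5e-04), with EGR2, DUSP1 and JUNB leading. YAP/TEAD target genes rose in 15 of 20 cases and fell in 2 (median 0.74, camera adjusted p = 6.5e-04), the growth factor binding protein IGFBP3 from 10.1 ± 4.36 to 1338 ± 88.0 and ANKRD1 from 9.31 ± 1.96 to 240.3 ± 12.9. These 3 calls and those of the 6 preceding lists held with an estimated correlation. ERBB receptors and ligands rose in 6 of 8 cases, TGFA by 4.05 and HBEGF by 2.52, and AREG fell by 3.26 on the log2 scale (camera adjusted p = 0.0205, adjusted p = 0.0606 with an estimated correlation). Of the ABC drug transporters, 5 of 6 rose, ABCC3 by 3.75 and ABCG2 by 2.53 (camera adjusted p = 0.0207, adjusted p = 0.0606 with an estimated correlation). The BCL2 family had 9 of 14 genes higher, BIK by 3.87 and PMAIP1 by 2.17, and 3 lower (camera adjusted p = 0.0267, adjusted p = 0.0606 with an estimated correlation), and missed the threshold on edgeR's estimates (camera adjusted p = 0.0911). Of the vestigial-like, TEAD and YAP/TAZ genes, 7 of 9 rose, VGLL3 by 5.96 and TEAD3 by 0.75, and 2 fell (camera adjusted p = 0.0267, adjusted p = 0.137 with an estimated correlation). VGLL1, the activated gene, is on this list and among those that rose, so the call rests in part on the activated gene itself. Apart from the p53 list, the counts of these called lists were the same when adjusted over the list alone.

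The 8 lists that did not pass in FULVR-1 against VGLL1 cells (camera adjusted p from 0.0726 to 0.917) included luminal markers, with 5 higher and 8 lower of 16 (median -0.14), with the transcription factor SPDEF at -2.66 and ELF3 at 1.97. Mesenchymal markers had 5 higher and 2 lower of 10 (median 0.77, 7 higher when adjusted over the list alone), with TGFBI at 6.83, fibronectin FN1 at 4.82 and TWIST1 at -2.77. Medians were -0.37 for cholesterol synthesis genes, 0.44 for hypoxia and glycolysis genes, 0.62 for unfolded protein and ATF4 response genes, 0.11 for the neighbours of VGLL1 and -0.11 for histone genes. Of the markers of non-epithelial cells, 3 of 10 rose, CDH5, CD14 and ACTA2 (median 0.34, camera adjusted p = 0.287), with CD14 at 49.1 ± 3.33 and ACTA2 at 73.4 ± 5.55 normalised counts in FULVR-1.

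Across all genes, 9323 differed between FULVR-1 and VGLL1 cells (limma, adjusted p under 0.05), 4686 higher and 4637 lower, of which 1767 and 1138 by at least 2-fold. Without FULVR-1 replicate 2, which stood apart from its group, the count was 9189. Other large decreases were those of GFRA1, a receptor for glial cell line-derived neurotrophic factor, at -9.62 and the semaphorin receptor PLXNA4 at -9.47. LINC00052 (ratio 1160.4, counting interval 402 to 5701) and the cytokine IL24 (ratio 171, counting interval 61.0 to 872) fell as well. So did the cytokine IL20 at -7.77, PCDH10 at -7.70 and HAPLN1 at -7.10. The largest increases besides CDH5 (ratio 596, counting interval 207 to 2939) and EPAS1 were those of the lipoxygenase ALOX5 (8.14), the integrin ITGB6 (7.47), the netrin NTN4 (7.35), FOXJ1 (7.30), the deiodinase DIO2 (7.28), S100P (7.19), ATG9B (7.09) and ADGRF1 (ratio 679, counting interval 119 to 26341). Counting intervals here and elsewhere cover counting error only. All 100 genes named in this comparison that passed the threshold also passed it under every alternative run.

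**Figure D2:**
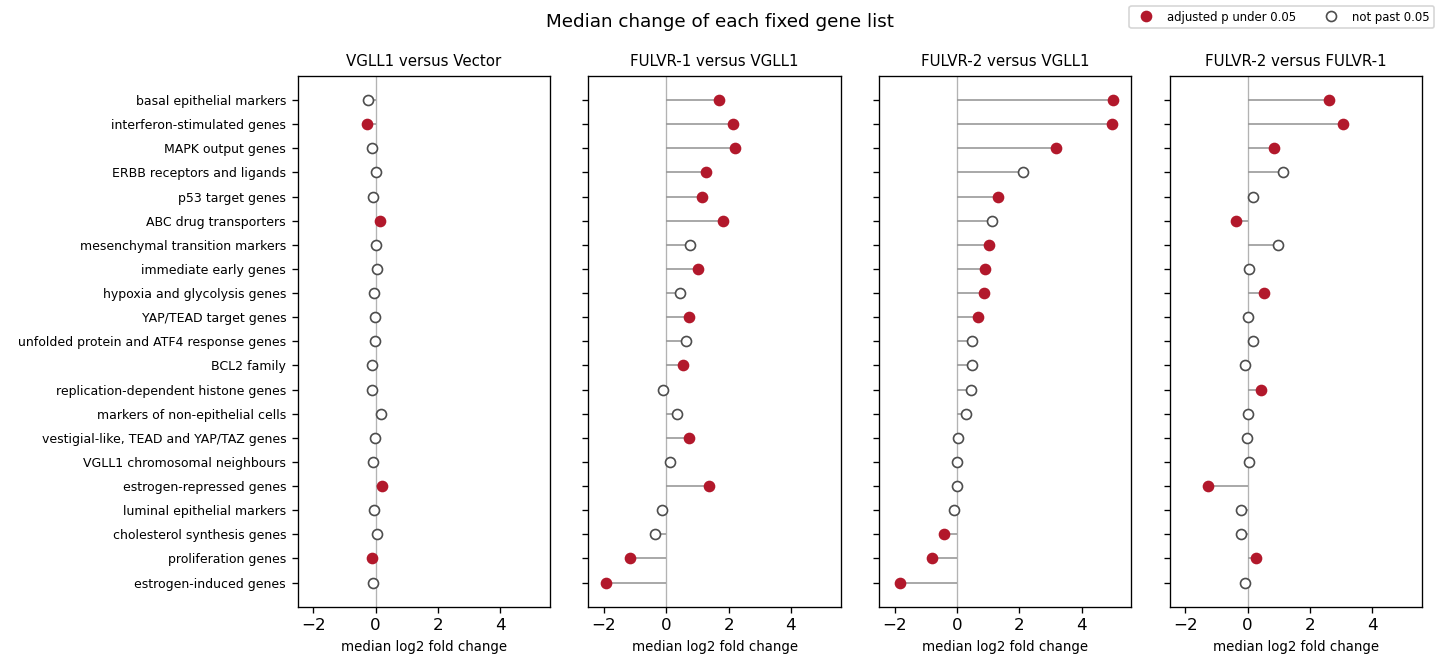
Median log2 fold change (x axis) of the 21 gene lists that could be tested (y axis) in the 4 main comparisons, where a filled symbol marks a camera adjusted p under 0.05. Interferon-stimulated genes had medians of -0.29 in VGLL1 against Vector cells, 2.15 and 4.96 in FULVR-1 and FULVR-2 against VGLL1 cells, and 3.08 in FULVR-2 against FULVR-1 cells.

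FULVR-2 cells, resistant at 1000 nM fulvestrant, were set against VGLL1 cells in the same way. ESR1 fell from 2697 ± 118 to 266 ± 22.9, 10.1-fold lower (limma, adjusted p = 1.6e-18), and GREB1, TFF1 and PGR fell 159.7-, 23.4- and 327-fold to 66.5 ± 7.18, 197 ± 15.7 and 2.12 ± 1.06. EGFR rose 25.2-fold to 1602 ± 77.9 (limma, adjusted p = 4.9e-16). Interferon-stimulated genes rose strongly, IFIT2 from 9.17 ± 3.95 to 4208 ± 212 and IFIT3 from 9.90 ± 0.919 to 4414 ± 4.50. CYR61 rose by 0.25 on the log2 scale (limma, adjusted p = 0.0097), a call lost in DESeq2 (adjusted p = 0.0534), and CTGF had a log2 fold change of -0.06 (limma, adjusted p = 0.719).

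All 21 interferon-stimulated genes rose in FULVR-2 cells (median log2 fold change 4.96, camera adjusted p = 5.1e-13), including the antiviral genes MX2 (ratio 665, counting interval 219.9 to 3125) and OAS2 (8.01). Estrogen-induced genes fell in 25 of 29 cases (median -1.82, camera adjusted p = 1.0e-08), CA12 at -8.20 and PDZK1 at -6.94, and NRIP1, AREG and SUSD3 rose. Basal epithelial markers rose in 11 of 12 cases (median 5.02, also with KRT14 at its bound, camera adjusted p = 2.4e-06), with KRT16 at 7.64, LAMC2 at 7.58, S100A2 at 6.08 and LAMB3 at 6.03, while TP63, a transcription factor of basal cells, fell. Targets of p53 rose in 16 of 16 cases (median 1.31, camera adjusted p = 9.2e-07), FAS by 4.53 and CDKN1A by 1.85. MAPK output genes rose in 12 of 13 cases (median 3.17, camera adjusted p = 2.3e-05), FOSL1 from 8.55 ± 2.27 to 915 ± 27.7 and DUSP4 from 34.9 ± 2.99 to 1725 ± 76.8. These 5 calls held with an estimated correlation.

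A further 6 lists passed in FULVR-2 against VGLL1 cells with the preset correlation only. All 24 proliferation genes fell (median -0.81, camera adjusted p = 4.9e-09, adjusted p = 0.0586 with an estimated correlation), with MYBL2 at -1.55 and TOP2A at -1.24. Immediate early genes rose in 11 and fell in 2 of 14 cases (camera adjusted p = 0.00228, adjusted p = 0.0607 with an estimated correlation), with ATF3 at 3.90 and KLF6 at 2.69. Hypoxia and glycolysis genes rose in 14 and fell in 4 of 19 cases (camera adjusted p = 0.00496, adjusted p = 0.0586 with an estimated correlation), with ADM at 2.05 and LOX at 2.32. YAP/TEAD target genes rose in 15 and fell in 3 of 20 cases (camera adjusted p = 0.00713, adjusted p = 0.0774 with an estimated correlation), with IGFBP3 at 6.69 and NUAK2 at 4.25. Cholesterol synthesis genes fell in 11 and rose in 3 of 19 cases (camera adjusted p = 0.0143, adjusted p = 0.402 with an estimated correlation), with LSS at -1.36 and FDFT1 at -1.29. Mesenchymal markers rose in 6 and fell in 2 of 10 cases (camera adjusted p = 0.0466, adjusted p = 0.101 with an estimated correlation), with TGFBI at 8.22 and FN1 at 5.59. That mesenchymal call was also lost without VGLL1 replicate 1 (camera adjusted p = 0.0576), FULVR-2 replicate 2 (0.0606) or FULVR-2 replicate 3 (0.0745), with a pseudocount of 0.1 (0.0547), quantile normalisation (0.052) and sample quality weights (0.0508). Every count of the 11 called lists was the same when adjusted over the list alone.

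Among the 10 lists that did not pass in this comparison (camera adjusted p from 0.0791 to 0.781), estrogen-repressed genes had 6 higher and 4 lower of 14, with BCAS1 at 1.04, BMF at -1.59 and DEPTOR at -0.90, and their mean of -0.04 and the direction of the test, upward, differed in sign. ERBB receptors and ligands had 5 higher and 3 lower of 8 (median 2.11), with HBEGF at 4.80 and TGFA at 4.73. Luminal markers had 6 higher and 8 lower of 16 (median -0.10), with SPDEF at -6.06 and the androgen receptor AR at -1.99. Medians were 0.05 for vestigial-like, TEAD and YAP/TAZ genes, 0.48 for unfolded protein and ATF4 response genes, 0.47 for the BCL2 family, 1.12 for ABC drug transporters, 0.02 for the neighbours of VGLL1 and 0.47 for histone genes. Of the markers of non-epithelial cells, 3 of 10 rose, CDH5, ACTA2 and CD14, and MYH11 fell (median 0.30). CD14 stood at 17.5 ± 8.34 normalised counts, and its call was lost without VGLL1 replicate 2, FULVR-2 replicate 1 or FULVR-2 replicate 3 (limma, adjusted p = 0.115, 0.0619 and 0.0672) and with a pseudocount of 0.1 (limma, adjusted p = 0.103).

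In total, 9883 genes differed between FULVR-2 and VGLL1 cells (limma, adjusted p under 0.05), 5032 higher and 4851 lower, of which 1861 and 1456 by at least 2-fold. Besides IFIT2, IFIT3 and MX2, large increases were those of CDH5 (ratio 1559, counting interval 535 to 7592), SAMD9 (9.62 on the log2 scale) and its relative SAMD9L (8.79), the retinol transporter STRA6 (9.28), the transglutaminase TGM2 (8.53), SH3RF2 (ratio 689, counting interval 229 to 3255) and RSAD2 (8.37), an antiviral gene. BCL2 fell from 1859.6 ± 76.2 to 2.03 ± 2.06, GFRA1 fell to a log2 fold change of -9.28, PCDH10 of -9.07, PLXNA4 of -8.88, LINC00052 of -8.72 and the chemokine receptor ACKR3 of -8.10, and HAPLN1 fell to a low count (ratio 698, counting interval 181 to 5422). IL20 and MALRD1 had no read in FULVR-2 and were at least 520.2-fold and at least 301-fold lower, taking 3 counts over the group as the floor. Of 99 named genes past the threshold, 97 passed it under every alternative run, the exceptions being CYR61 and CD14.

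FULVR-2 was set against FULVR-1 to ask how the resistant lines differed from each other, and this comparison is also the test of whether their changes against VGLL1 cells differed. The 3 interferon lambda genes rose in FULVR-2, IFNL1 from 2.97 ± 2.98 to 273 ± 39.0, IFNL2 from 2.69 ± 1.49 to 237 ± 24.0 and IFNL3 from 3.90 ± 3.46 to 259.5 ± 25.8, although reads of these near-identical copies cannot be assigned with certainty. The chemokine CCL5 rose from 19.2 ± 5.86 to 854 ± 113 and SERPINE1, an inhibitor of plasminogen activation, from 79.6 ± 2.75 to 4099.8 ± 49.4. BMF fell from 1270.0 ± 259 to 52.7 ± 9.12. ESR1 was 2.21-fold lower in FULVR-2 (log2 fold change -1.14 ± 0.06 (SE)), EGFR 2.94-fold higher (1.56 ± 0.13 (SE)) and CTGF 2.39-fold lower (-1.25 ± 0.15 (SE)), each past the threshold (limma, adjusted p = 2.2e-11, 9.0e-09 and 9.2e-07).

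Each of the 21 interferon-stimulated genes was higher in FULVR-2 than in FULVR-1 cells (median log2 fold change 3.08, camera adjusted p = 2.3e-14), IFIT2 by 4.95, IFIT3 by 4.79 and IFI44L by 4.60. Estrogen-repressed genes fell in 13 of 14 cases (median -1.27, camera adjusted p = 1.1e-06), with PSCA at -4.09 and BCAS1 at -2.11. Basal epithelial markers rose in 11 of 12 cases (median 2.61, also with KRT14 at its bound, camera adjusted p = 1.0e-05), with S100A2 at 4.33 and KRT17 at 3.46, and TP63 fell. KRT14 had no read in FULVR-1 and was at least 19.9-fold higher in FULVR-2, though KRT14, KRT16 and KRT17 are close copies of each other and their counts are less certain. These 3 calls held with an estimated correlation. Hypoxia and glycolysis genes rose in 14 and fell in 3 of 19 cases (median 0.54, camera adjusted p = 0.00474, adjusted p = 0.0725 with an estimated correlation), with LDHA at 1.26 and EGLN3 at -2.22. MAPK output genes rose in 9 and fell in 1 of 13 cases (median 0.84, camera adjusted p = 0.00972, adjusted p = 0.208 with an estimated correlation), with FOSL1 at 3.37 and DUSP5 at 2.15. Proliferation genes rose in 14 of 24 cases, 15 when adjusted over the list alone, with AURKB at 0.64, and MCM6 fell (median 0.28, camera adjusted p = 0.00724, adjusted p = 0.423 with an estimated correlation). Histone genes, whose copies are too alike for certain counts, rose in 7 of 13 cases, 6 when adjusted over the list alone (median 0.44, camera adjusted p = 0.0168, adjusted p = 0.213 with an estimated correlation). All 6 ABC drug transporters fell (median -0.37, camera adjusted p = 0.0343, adjusted p = 0.145 with an estimated correlation), a call that for ABCC2 and ABCC4 did not hold under every alternative. On edgeR's estimates the proliferation, histone and ABC lists missed the threshold too (camera adjusted p = 0.0839, 0.125 and 0.114). The other called lists had the same counts when adjusted over the list alone.

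The 13 lists that did not pass between the resistant lines (camera adjusted p from 0.078 to 0.935) included estrogen-induced genes, with 12 higher and 14 lower of 29, AREG at 4.19, IGFBP4 at 2.62 and TFF3 at -2.52. YAP/TEAD target genes had 7 higher, 8 when adjusted over the list alone, and 7 lower of 20, with the receptor kinase AXL at 2.63 and TGFB2 at -2.39. Luminal markers had 5 higher and 9 lower of 16 (median -0.23), with SPDEF at -3.40 and FOXA1 at -1.69. Medians were 1.12 for ERBB receptors and ligands, 0.04 for immediate early genes, 0.98 for mesenchymal markers, -0.20 for cholesterol synthesis genes, 0.18 for unfolded protein and ATF4 response genes, 0.18 for p53 targets, -0.10 for the BCL2 family and 0.06 for the neighbours of VGLL1. Without FULVR-1 replicate 2 the cholesterol list passed (camera adjusted p = 0.0273). Vestigial-like, TEAD and YAP/TAZ genes had 3 higher and 3 lower of 9, with WWTR1 at 0.75 and TEAD2 at -0.79. Markers of non-epithelial cells had 2 higher and 3 lower of 10 (median 0.01), and for these and the estrogen-induced genes the median, the mean and the direction of the test differed in sign.

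Altogether 8236 genes differed between FULVR-2 and FULVR-1 (limma, adjusted p under 0.05), 4223 higher and 4013 lower in FULVR-2, of which 815 and 1030 by at least 2-fold, and the count was 8031 without FULVR-1 replicate 2. Other large increases were those of the tensin TNS4 (7.58), FGFBP1 (6.35), SH3RF2 (5.99), TGM2 (5.16) and the acute-phase gene SAA1 (5.42), which shares sequence with a close copy and is uncertain. Large decreases besides that of BMF were those of SBK2 (-5.61), STUM (-4.54), SHISA2 (-4.51), CHRD (-4.17), DNAJC22 (-4.05), SYT12 (-3.94), DOCK11 (-3.85), CACNG4 (-3.85) and LBH (-3.83). They were named by the rule that asks for a mean of at least 100 in the higher group and no overlap of replicates. GREB1 and TFF1 had log2 fold changes of -0.86 and -0.50, CYR61 of -0.10 (limma, adjusted p = 0.294) and PGR, near 0 reads in both lines, a ratio of 6.45 with a counting interval of 0.789 to 299. Of 106 named genes past the threshold, 97 passed it under every alternative run, the exceptions being ABCC2, ABCC4, ARHGEF6, CD14, CDH5, PGR, SNAI2, VGLL1 and VWF. Dose and line cannot be separated in this design, since each line was kept in 1 dose.

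**Figure D3:**
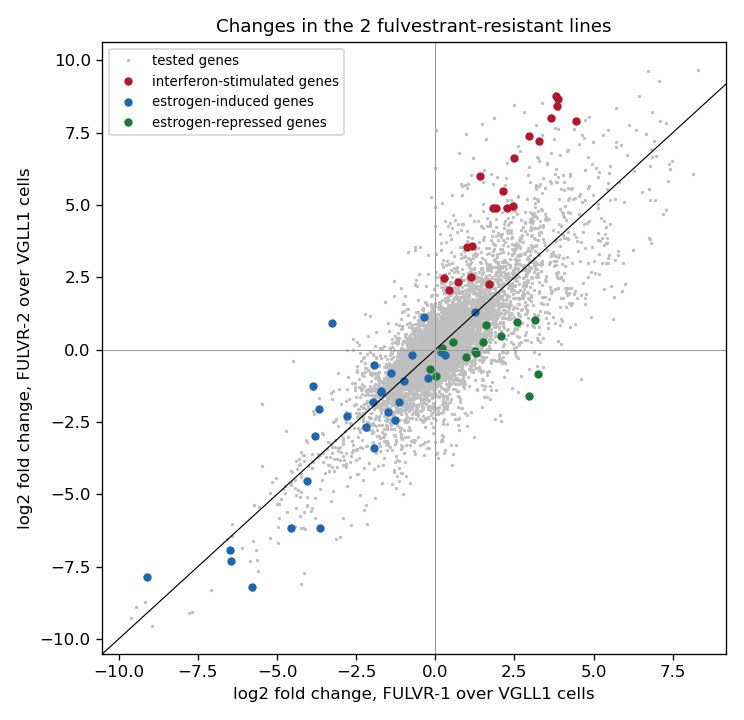
Log2 fold change against VGLL1 cells in FULVR-1 (x axis) and FULVR-2 (y axis), with a point per gene, interferon-stimulated genes in red, estrogen-induced genes in blue, estrogen-repressed genes in green, and the line of equality. The 21 interferon-stimulated genes had medians of 2.15 on the x axis and 4.96 on the y axis.

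Against Vector cells, ESR1 was 4.82-fold lower in FULVR-1 and 10.7-fold lower in FULVR-2, and EGFR 7.68-fold and 22.6-fold higher. GREB1 and TFF1 had log2 fold changes of -6.50 and -4.29 in FULVR-1 and -7.36 and -4.78 in FULVR-2, and PGR was lower by a ratio of 2404 in FULVR-1 (counting interval 441 to 97152) and 373 in FULVR-2. CTGF had log2 fold changes of 1.21 and -0.04 (limma, adjusted p = 7.8e-07 and 0.815) and CYR61 of 0.18 and 0.08 (limma, adjusted p = 0.0526 and 0.383). CYR61 in FULVR-1 passed the threshold without Vector replicate 2 or FULVR-1 replicate 1 (limma, adjusted p = 0.0231 and 0.048). In FULVR-1, 20 of 21 interferon-stimulated genes rose (camera adjusted p = 4.1e-07), 25 of 29 estrogen-induced genes fell, 26 when adjusted over the list alone (camera adjusted p = 4.7e-10), and all 24 proliferation genes fell (camera adjusted p = 4.8e-11). FULVR-2 had 21 of 21 interferon-stimulated genes higher (camera adjusted p = 1.2e-12), 24 of 29 estrogen-induced genes lower (camera adjusted p = 1.0e-08) and all 24 proliferation genes lower (camera adjusted p = 1.2e-09, adjusted p = 0.0525 with an estimated correlation). With the preset correlation 13 lists passed in FULVR-1 and 11 in FULVR-2, and with an estimated correlation 6 and 4 of these, among them the basal markers and p53 targets in both lines. In all, 9706 genes differed in FULVR-1, 4878 higher and 4828 lower, or 9475 without FULVR-1 replicate 2, and 9844 in FULVR-2, 4982 higher and 4862 lower.

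Of the genes called against VGLL1 cells, 3417 rose in both resistant lines, where independent lists would share 1690.1, and 3288 fell in both, against 1612. Opposite directions were found for 388 genes that rose in FULVR-1 and fell in FULVR-2 and for 406 that did the reverse, fewer than the 1629 and 1672 of independent lists. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.80 where simulated unchanged groups gave 0.50, and a covariance of 1.33 against a simulated 0.0169. The simulation held no changed gene, so its 0 shared calls on average were fixed in advance and no conclusion is drawn from them. How much spread between replicates adds to the shared calls when many genes differ was not simulated. The covariances argue against such spread, that of the shared VGLL1 libraries included, as the source of most of the covariance. The 3 VGLL1 libraries that both comparisons share cannot be split into parts of at least 2. A deviation common to all 3 may thus still account for part of the covariance and of the excess over independent lists. Genes higher in VGLL1 than in Vector cells and higher again in FULVR-1 numbered 161 (independent lists 114), and those lower in both 164 (108). In opposite directions 77 (113) rose and then fell and 110 (109) fell and then rose, and the covariance was 8.2e-04 against a simulated -0.0169. For FULVR-2 the same directions numbered 115 (123) and 113 (113). The excess there lay in the opposite ones, 153 (118) that rose and then fell and 169 (118) that fell and then rose, with a covariance of -0.0346 against -0.0170. Its correlation of -0.0975 against a simulated -0.499, and its share of genes with the same sign, 46.8% against 33.4%, were less opposite than in unchanged groups. In these 2 overlaps the shared VGLL1 libraries enter with opposite signs, which favours opposite directions. Part of the excess in FULVR-2 may come from that. With both resistant lines set against Vector instead, the same directions exceeded independent lists, 249 (119) and 208 (113) in FULVR-1 and 178 (121) and 155 (114) in FULVR-2. Genes that rose in VGLL1 and were below Vector in FULVR-2 numbered 82 (118), and the reverse 117 (116). The covariances were 0.0655 and 0.0301 against a simulated 0.0170 and 0.0170, and the shared Vector libraries favour the same direction, so part of this excess may come from them. Changing the reference adds the variance of the VGLL1-minus-Vector changes to each covariance, so a shift toward the same direction was built in. The direction found for FULVR-2 depended on the reference group for that reason, and no conclusion is drawn from it.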

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

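The tests of other splits, of length and GC content and of immune-cell RNA were chosen before their results were seen, and the test of the dose only afterwards. Between the resistant lines, 8236 genes had changes against VGLL1 cells that differed (limma, FULVR-2 against FULVR-1). As lists, estrogen-repressed genes had a median log2 fold change of FULVR-2 over FULVR-1 of -1.27, basal epithelial markers of 2.61 and interferon-stimulated genes of 3.08, and these differences passed camera with the preset and with an estimated correlation. MAPK output genes had a median of 0.845, hypoxia and glycolysis genes of 0.540, proliferation genes of 0.278, replication-dependent histone genes of 0.439 and ABC drug transporters of -0.368, and these passed with the preset correlation only.

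Interferon-stimulated genes were higher in FULVR-2 than in FULVR-1 in all 21 cases, beside higher IFNL1, IFNL2 and IFNL3. Of 10000 lists matched on transcript length and GC content, 0% had a median as high, and the highest reached 0.492, which argues against those properties as the cause. RNA of immune cells is argued against by their own transcripts: of 12 leukocyte markers fixed beforehand, 4 of them shared with the list of non-epithelial markers, 0 reached a mean of 50 in FULVR-2, and the highest was CD14 at 17.5, whereas IFIT3 stood at 4414 ± 4.50. The dose cannot be told apart from the line and its selection, since 0 lines were kept in both doses. A stronger interferon response of the FULVR-2 cells themselves may underlie the difference, as a hypothesis that stays untested, and reads shared between related genes on the list were not tested.

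For each of the 6 comparisons the 6 libraries can be split in 10 ways, too few for a share under 0.05, and 1 split, the real one, gave as many genes as the real grouping. The real split gave 666 genes for VGLL1 against Vector, where the highest other split gave 1. For FULVR-1 against VGLL1 it gave 9323, for FULVR-2 against VGLL1 9883, for FULVR-2 against FULVR-1 8236, for FULVR-1 against Vector 9706 and for FULVR-2 against Vector 9844, and the highest other split gave 0 in each of these 5. Every other split mixes the groups compared, so a difference between them widens the spread and lowers the count. No conclusion is drawn from these splits.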

How the results depend on the processing

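The counts of called genes in the 5 comparisons that involve a resistant line stayed within 1.5 times their main values under every alternative run. Which direction held more genes depended on the normalisation for both resistant lines against VGLL1. After quantile normalisation 4347 genes were higher and 5184 lower in FULVR-1, and 4634 higher and 5373 lower in FULVR-2. FULVR-2 against FULVR-1 kept more higher genes, 4281 against 4187 lower. For VGLL1 against Vector the main count of 666 became 412 with no filter on low values, which adds tests, and 2085 with sample quality weights (the cause was not tested), and it ranged from 46 to 553 when 1 replicate was left out, with 110 without Vector replicate 1, 172 without Vector replicate 2, 46 without VGLL1 replicate 1 and 72 without VGLL1 replicate 2. It was 553 without Vector replicate 3 and 548 without VGLL1 replicate 3. Fewer libraries account for part of the drop by construction, but which replicate was left out mattered more. The cause of the differences between replicates was not tested. Its 2-fold counts of 23 and 8 ranged from 1 to 54 and from 1 to 20, and elsewhere 2-fold counts moved past 1.5 times only with a mean of at least 50 required, which removes genes. Its split of higher and lower genes was 431 and 256 in edgeR and 287 and 541 with only the 2 groups compared. EGFR and CTGF, not past the threshold in these comparisons, and RBMX, past it in FULVR-1 against Vector, changed sign, and the cause was not tested. The log2 fold change of EGFR in VGLL1 against Vector ranged from -0.238 to 0.0473 with a replicate left out, and that of CTGF from -0.0538 to 0.118, with -0.0298 after quantile normalisation. CTGF ranged from -0.175 to 0.00343 in FULVR-2 against VGLL1 and from -0.154 to 0.0565 in FULVR-2 against Vector. RBMX in FULVR-1 against Vector became 0.00523 after quantile normalisation. Of the results compared across alternatives, 481 counts of genes (total, by direction and at 2-fold) stayed within 1.5 times and 49 moved, 2133 list tests were the same, 73 newly passed and 50 no longer passed, and 8724 values of named genes were the same, 239 no longer passed, 10 newly passed and 11 changed sign. A replicate block gave 876, 9406, 9988, 8350, 9795 and 9883 genes for VGLL1 against Vector, FULVR-1 and FULVR-2 against VGLL1, FULVR-2 against FULVR-1, and FULVR-1 and FULVR-2 against Vector. Each of these lay above the main count. Deviations of same-numbered libraries correlated at -0.0622 to 0.0715 and those of differently numbered ones at -0.0937 to 0.0602, so no clear pairing by number was seen. These correlations run over all tested genes and do not exclude a weak pairing. Depth limits low genes, for which 0 reads allowed up to 0.326 CPM.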

Other observations

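The tests of carry-over, chance values, length and GC content in FULVR-1 replicate 2, a sample of another group and runs of neighbouring genes were chosen only after the results were seen, and the genes named here outside the fixed rule were chosen after their values were seen. Of the genes called in both resistant lines against VGLL1 cells, 388 rose in FULVR-1 and fell in FULVR-2, and 406 did the reverse. The difference between the lines passed the threshold for all of them, which opposite calls against the same VGLL1 cells nearly guarantee. Independent lists would give more, 1629 and 1672. BMF rose to a log2 fold change of 2.97 in FULVR-1 and fell to -1.59 in FULVR-2. ATP2A3, a calcium pump, stood at 3429 ± 81.5 in Vector, 4511 ± 162 in VGLL1, 5600.0 ± 550.3 in FULVR-1 and 411 ± 54.5 in FULVR-2. The epithelial gene S100A14 had log2 fold changes of -1.60 and 1.63, and TNS3, a tensin, of 2.61 and -0.29, where its relative TNS4 rose by 7.58 from FULVR-1 to FULVR-2. AREG, a ligand of EGFR, fell to -3.26 in FULVR-1 and rose to 0.92 in FULVR-2.

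Falls of at least 2-fold in VGLL1 against Vector cells were seen in 8 genes, a number that was 1 to 20 under the alternatives. Of these, 7 were higher in FULVR-2 than in Vector. The calcium channel RYR1 stood at 93.6 in Vector, 17.8 in VGLL1, 1294 in FULVR-1 and 4097 in FULVR-2. OAS1, KLK7, SLC15A3, ANKRD33B, BCAT1 and IGFL1 were also higher, while CLCN4 was not. Across all tested genes 35.7% rose in FULVR-2 against Vector, and 38.7% of the 4231 with a Vector mean in the range of these 8. KLK7, SLC15A3, ANKRD33B and IGFL1 were too low in Vector and VGLL1 cells to pass the filter without the resistant lines. A rise of theirs in a resistant line was thus largely built in. Carry-over of FULVR-2 RNA or reads into the Vector libraries would need a median share of 1.85%, and at least 0.516%, yet VGLL1 itself stood in Vector at 0.0921% of its FULVR-2 level, which argues against it. Chance highs in Vector or lows in VGLL1 are argued against for RYR1, whose adjusted p over all tested genes was 1.8e-11 and at most 7.7e-10 with any 1 library left out. For the other 7 genes chance stays open. Of these, 2 stayed past the threshold with any 1 library left out, OAS1 and KLK7, with adjusted p = 0.00383 and 0.00365 over all libraries and at most 0.0277 and 0.0230 with 1 left out, and the call of each of the other 5 was lost at least once. Loss of a minor subset of cells on deriving the VGLL1 line may also give such values, and was not tested.

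FULVR-1 replicate 2 differed from replicates 1 and 3 by more than other replicates did, and no biological explanation was tested. Transcript length and GC content explained 26.5% of the variance across genes of its difference from the others, against 31.4% for replicate 3 of the same group. Each library was set against the mean of the others in its group, so the value of replicate 3 includes replicate 2 and is no separate yardstick. A contribution of length and GC content stays open. As the whole cause they are argued against, because the SD across genes went only from 0.202 to 0.174 on their removal. The highest SD of any other library before removal was 0.145, in FULVR-1 replicate 3, whose value again includes replicate 2. Outside FULVR-1 the highest was 0.135. A sample of another group under this label is argued against by its rank correlation of 0.994 with a library of its own group and of at most 0.950 outside it, a lead of 0.0439. A difference in handling or library preparation of this sample may remain, since the labels give no batch.

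Runs of neighbouring genes that changed together were looked for with a running median over 31 neighbouring genes, among 10856 genes ordered along the chromosomes, and set against 1000 random orders. In FULVR-1 against VGLL1 the largest run was a fall with a median log2 fold change of 0.738 in size, from RRP1B to DIP2A around LINC01547, where 27 of 31 genes fell (permutation p = 0.004). In FULVR-2 against VGLL1 it was 0.972, from KLHL2 to CASP3 around SAP30, where 25 rose (permutation p = 0.001, the smallest these permutations can give). The same stretches had medians of 0.708 in FULVR-1 and -0.877 in FULVR-2. Between FULVR-2 and FULVR-1 the largest was 0.572, from SLC16A2 to ARMCX1 around RPS6KA6 (permutation p = 0.002). Gains or losses of chromosome segments in cells of the resistant lines are a candidate explanation, as is regulation shared by neighbours, and DNA copies were not measured.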
